A study of Rattus norvegicus with 16 samples.

How the data were processed

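Gene expression was measured on 16 Affymetrix arrays, 1 for each combination of 4 rat brain regions and 4 treatments. Both parts of the habenula were sampled, lateral (LHb) and medial (MHb), along with a pair of hindbrain nuclei, the medial vestibular (MVe) and the solitary nucleus (Sol). The treatments were sevoflurane, oxygen alone (O2), propofol and Intralipos, the lipid emulsion that serves as the vehicle of propofol. Per the labels' protocols, the regions were cut by laser from frozen, Nissl-stained sections, total RNA was extracted from the fragments, and biotin-labelled cDNA was made from 100 ng of it with a GeneChip WT PLUS kit.

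The deposited values are log2 signals, 1 per probe set and array, normalized by the authors with Affymetrix Expression Console 1.3.0, per the submitters' processing notes. The summarization method and the genome build are not given in the sources used here. The log2 scale is not stated either and was taken from the values, which run from about 2 to 20, so every fold given below rests on it. The deposited table held 24834 probe sets (called probes below), of which 94 were control probes without rat sequence. Probes were named through the platform's annotation, updated by gene identifier. There were 15049 probes with 1 gene symbol, 0 with several and 9691 without a symbol here, and unnamed probes entered no test of genes. Where a gene had more than 1 probe, the probe with the highest mean over the 16 arrays was kept, which left 15037 genes. No filter on dim genes and no further normalization were applied.

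The values fell into a pair of array sets. The mean over all probes lay between 7.20 and 7.21 in the sevoflurane and O2 arrays and between 6.97 and 6.99 in the propofol and Intralipos arrays, so the sets look as if they had been normalized separately. Sevoflurane minus O2 and propofol minus Intralipos are differences within a set. Intralipos minus O2 is a difference between sets, and treatment and set cannot be told apart in it.

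Because each region and treatment had 1 array, the 4 regions stood in for replicates of a treatment. A linear model with treatment and region as terms was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 9 residual degrees of freedom, two-sided tests), and p-values were adjusted over the 15037 genes by the Benjamini-Hochberg method, with a threshold of 0.05. The difference of both anesthetic effects, each against its own control, was tested as 1 contrast, and the 4 treatments together by a moderated F test. The habenula (LHb and MHb) was compared with the hindbrain (Sol and MVe) in a fit with 6 residual degrees of freedom for the anesthetic effects. Region contrasts used the 4 treatments in the place of replicates. The labels do not tie the regions to single rats, so arrays that share a rat may be counted as independent and the p-values may be too small. Errors written with ± are moderated standard errors of the fitted log2 change, unless another measure is named. They rest on a gene's residual spread over all arrays of the fit. They do not measure its spread over the regions or treatments of the comparison at hand, which can be larger. Differences between single arrays of a region have no replicate check and no test.

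Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists of a contrast. The 36 lists held 517 distinct genes, of which 462 were measured, and covered stress and activity responses, receptors, channels and transmitters, and markers of the regions, of neighbouring tissue and of other cell types. Each list was also tested with the correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in 1 direction. Within a region, a list's median difference was placed among 10000 random lists of the same size matched on mean expression with numpy 2.4.6 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

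The tests of the comparisons, the 36 lists and the rule for naming genes were fixed before the data were examined; the tests of explanations and 1 added list in the closing section were not. For each contrast the rule named the 10 largest changes in each direction among genes past the threshold with the same sign in every pair of arrays, and, where fewer than 5 passed in a direction, the 5 with the smallest p, described as not past the threshold. Up to 4 members with the largest change were named from each list described, with any member past the threshold. Within each region pair the 4 largest differences in each direction were named among genes whose higher array reached the median of all gene values. Fos, Npas4, Arc, Egr1 and Junb were named in every region pair. Genes with placeholder names were counted and not named. Genes outside the rule are said to have been chosen after their values were seen.

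The fits were tested on simulated arrays made for the 15037 genes, with 50 genes changed at each of 4 sizes. Each change was equal in every array of the changed group, and noise was independent between arrays. The shares below therefore do not hold for changes that vary between regions, for arrays that share a rat or for differences between array sets. For sevoflurane against O2, 12.0% of genes changed by 0.5 on the log2 scale were called, 66.0% of those changed by 1, 98.0% at 2 and 100% at 3. The shares for propofol against Intralipos were 14.0%, 80.0%, 98.0% and 100%, and those for the difference of the anesthetic effects were 2.0%, 38.0%, 94.0% and 100%. Between LHb and MHb they were 16.0%, 86.0%, 100% and 100%. Unchanged genes were called in 0.0337%, 0.0202%, 0.0472% and 0.0337% of cases in these comparisons. In 4000 simulated lists of 21 unchanged genes, 5.10% lay above the 95th percentile of their random lists and 4.90% below the 5th. Those lists were drawn at random with noise independent between genes, so shares near 5% follow from the setting. They do not hold for lists whose genes move together, and the percentiles given below are not p-values. The number of arrays limits the precision.

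Alternatives were quantile normalization over all arrays, median centring, a filter on dim genes, the mean of a gene's probes, another variance model, array weights, the arrays of the compared groups alone, a threshold of 0.1, and fits without each array or region. The effect of these is given in the closing section. No probe position on the genome was used.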

Results

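The data describe the transcriptomes of 4 brain regions of male Wistar rats after 60 minutes of treatment. Sevoflurane, an inhaled anesthetic, was given at 2.4%, and propofol, an intravenous anesthetic, at 36 mg/kg per hour after a bolus of 10 mg/kg. Control rats received O2 alone or Intralipos, an emulsion with 10% lipid, and all rats breathed 40% oxygen at 6 L/min. Each of the 16 arrays held 1 region of 1 treatment, which gave 4 arrays per treatment and 4 per region. Pearson correlations across genes, which are not independent replicates, lay between 0.991 and 0.994 for an anesthetic and its own control in the same region. They lay between 0.963 and 0.966 for LHb against MHb and between 0.960 and 0.963 for Sol against MVe under the same treatment, so the regions differed more than the treatments.

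The first question was which genes respond to sevoflurane across the regions. The highest values relative to O2 belonged to immediate early genes, which neurons transcribe within minutes of activation, and to genes that glucocorticoids induce. The kinase gene Sgk1, a glucocorticoid target, was 1.74 ± 0.28 higher on the log2 scale (adjusted p = 0.127), and the transcription factor genes Junb and Egr1 were 1.86 ± 0.33 (0.222) and 3.40 ± 0.64 (0.280) higher, each in 4 of 4 regions. None of the 15037 genes passed limma's test after adjustment (0 genes), while 751 had an unadjusted p under 0.05, 420 higher and 331 lower. That is about the share of genes that falls under 0.05 when none of them change. The matricellular gene Ccn1 (1.77 ± 0.38) and the gene Slc35c2 (0.77 ± 0.17) were the next highest by p, both with an adjusted p of 0.655. On the lower side Pmf1 (-0.72 ± 0.16), Ghdc (-0.60 ± 0.15) and the Wnt ligand gene Wnt5a (-0.75 ± 0.19) had an adjusted p of 0.655 and were lower in 4 of 4 regions. Il17c, which encodes an interleukin, was at -0.85 ± 0.22 and lower in 3 of 4 regions (0.655), and Klri2 was at -0.62 ± 0.16 and lower in 4 of 4 (0.684).

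The immediate early genes stood higher as a group after sevoflurane, with 37 of 45 measured members above 0 and a list median of 0.26 (camera adjusted p = 1.2e-14). That call was lost at an adjusted p = 0.145 with an estimated correlation. Over all genes 0 members passed, while adjusted over the list alone 16 were higher and 1 was lower. Besides Egr1, the largest values were those of the nuclear receptor gene Nr4a1 (2.69 ± 0.64), the transcription factor gene Fos (2.42 ± 0.58) and the endothelial early response gene Apold1 (1.95 ± 0.45), each with an adjusted p of 0.655 over all genes. The glucocorticoid-responsive genes rose as a group (camera adjusted p = 2.0e-08), with 20 of 23 members above 0 and a list median of 0.28, and kept the call at an adjusted p = 0.0162 with an estimated correlation. Of these, 0 passed over all genes and 6 were higher when adjusted over the list alone. After Sgk1, the largest were the phosphatase gene Dusp1 (1.49 ± 0.43, adjusted p = 0.779), the iron-binding lipocalin gene Lcn2 (0.85 ± 0.19, 0.655) and the cell cycle inhibitor gene Cdkn1a (0.83 ± 0.23, 0.778). Dusp1 and Per1 were the 2 measured genes that this list shares with the immediate early genes.

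Oligodendrocyte marker genes were lower after sevoflurane as a group, with 9 of 13 members below 0 and a median of -0.17 (camera adjusted p = 0.0434). This call was lost at an adjusted p = 0.830 with an estimated correlation, and with LHb (0.377) or MHb (0.549) left out. Its largest members were the myelin lipid enzyme gene Ugt8 (-0.53 ± 0.21, adjusted p = 0.975), the myelin protein genes Mbp (-0.41 ± 0.20, 0.982) and Mog (-0.31 ± 0.16, 0.982), and Mobp (-0.30 ± 0.18, 0.989), and 0 passed when adjusted over the list alone. The other lists had camera adjusted p-values from 0.0606, shared by the FoxO-responsive, ionotropic glutamate receptor and neuropeptide genes, to 0.981. GABA-A receptor subunit genes, which encode a main target of both anesthetics, had a median of 0.03, with the test pointing lower (0.753). Regions stood in for replicates and may share rats, so these p-values may be too small. The count of 0 genes became 8 without the LHb sevoflurane array and 1 without the Sol O2 array, and 2 with trend and robust variance estimates. The 8 genes, chosen after their values were seen, were Egr1 (4.22 ± 0.56), Nr4a1 (3.60 ± 0.51), Fos (3.31 ± 0.41), Apold1 (2.51 ± 0.40), Junb (2.26 ± 0.30), Dusp1 (2.09 ± 0.34), Nr4a3 (1.56 ± 0.25) and Lcn2 (1.09 ± 0.17).

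The next question was which genes respond to propofol across the regions, relative to its lipid vehicle. A stress-induced inhibitor of growth signalling, Ddit4, an inhibitor of the inflammatory transcription factor NF-kB, Nfkbia, and an olfactory receptor gene, Or4c110, were lower after propofol in 4 of 4 regions. Ddit4 fell by 1.51 ± 0.20 on the log2 scale, a 2.85-fold difference (adjusted p = 0.0082). Nfkbia fell by 1.23 ± 0.19 (0.0239) and Or4c110 fell by 1.18 ± 0.18 (0.0239). These were the 3 genes that passed limma's test, and 1040 genes had an unadjusted p under 0.05, 578 higher and 462 lower. Relative to the region's average over treatments, Ddit4 was at 1.07 with Intralipos, -0.44 with propofol, -0.58 with O2 and -0.06 with sevoflurane. Nfkbia was at 1.10, -0.14, -0.63 and -0.33 in that order. Both genes stood highest in the Intralipos arrays, so a rise in this control cannot be told apart from a fall with propofol. The O2 and sevoflurane arrays belong to the other array set.

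None of the higher genes passed. The neuropeptide precursor gene Pnoc (1.00 ± 0.19) and the phospholipid-modifying enzyme gene Plaat3 (1.04 ± 0.19) had an adjusted p of 0.146. Mrgpre (0.86 ± 0.18), the nicotinic receptor subunit gene Chrnb4 (0.80 ± 0.17) and the retinol saturase gene Retsat (0.73 ± 0.16) had 0.301, 0.301 and 0.339. On the lower side Sclt1 (-0.76 ± 0.15, 0.192), Gmppb (-0.94 ± 0.19, 0.279), the antiviral gene Oas1a (-1.40 ± 0.30, 0.301), Gnat1 (-0.81 ± 0.18, 0.404) and the receptor kinase gene Grk4 (-0.79 ± 0.18, 0.530) did not pass. All of these genes had the same sign in 4 of 4 regions.

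The glucocorticoid-responsive genes were lower after propofol as a group, with 17 of 23 below 0 and a median of -0.10 (camera adjusted p = 0.0047; adjusted p = 0.189 with an estimated correlation). Ddit4 and Nfkbia were the 2 members that passed over all genes, and 4 were lower when adjusted over the list alone. Sgk1 was at -0.83 ± 0.28 (0.640) and the metabolic kinase gene Pdk4 at -0.75 ± 0.21 (0.623). Neuropeptide genes were higher, 21 of 28 above 0 with a median of 0.16 (0.0166; adjusted p = 0.189 with an estimated correlation). Adjusted over the list alone 1 was higher and over all genes 0 were, and the enkephalin precursor gene Penk followed Pnoc at 0.74 ± 0.23 (0.640). The tachykinin gene Tac3 was at 0.61 ± 0.37 (0.811) and Npy at -0.51 ± 0.24 (0.721).

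Markers of tissue type moved along with these groups. Choroid plexus marker genes were higher, 10 of 11 above 0 with a median of 0.47 (camera adjusted p = 0.0019; adjusted p = 0.459 with an estimated correlation), with 2 higher when adjusted over the list alone and 0 over all genes. Ttr, the abundant choroid plexus transport protein gene, was at 1.69 ± 0.93 (0.773), Kl at 1.14 ± 0.36 (0.640), Otx2 at 0.84 ± 0.28 (0.640) and Kcnj13 at 0.73 ± 0.38 (0.754). Neuron marker genes were higher, 10 of 13 above 0 with a median of 0.19 (0.0222; adjusted p = 0.399 with an estimated correlation), led by the glutamate transporter gene Slc17a6 (0.45 ± 0.16, 0.646) and Eno2 (0.45 ± 0.18, 0.671). Astrocyte marker genes were lower, 10 of 11 below 0 with a median of -0.16 (0.0441; adjusted p = 0.486 with an estimated correlation), with Gfap at -0.42 ± 0.21 (0.736), and 0 members of either list passed when adjusted over the list alone. The immediate early genes had 28 of 45 members above 0 and were not called (0.186). The other lists had adjusted p-values from 0.0771, for ionotropic glutamate receptor genes, to 0.980.

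Regions stood in for replicates and may share rats, so the p-values for propofol may be too small. The count of 3 genes became 0 without the LHb propofol, LHb Intralipos or MHb Intralipos array, and 1 without the MHb propofol or Sol Intralipos array. It was 1 in a fit of the 8 arrays of both groups alone and 1 over all probes that are not controls. Among the lists, the glucocorticoid-responsive genes kept their call without each region. The neuropeptide genes lost it without Sol (0.0848) or MVe (0.0695) and the choroid plexus genes without MVe (0.0709). The neuron genes lost it without MHb (0.158), Sol (0.119) or MVe (0.0695) and the astrocyte genes without LHb (0.197), Sol (0.124) or MVe (0.164).

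A direct test asked where the anesthetics, each against its own control, differ. Sgk1 and Ddit4, a kinase gene and a stress-response gene that glucocorticoids induce, had a higher effect with sevoflurane than with propofol. The difference was 2.57 ± 0.39 for Sgk1 (adjusted p = 0.0363) and 2.03 ± 0.28 for Ddit4 (0.0163), with the same sign in 4 of 4 regions. Nfkbia had a difference of 1.54 ± 0.26 that did not pass (0.0906). In the sevoflurane comparison alone Ddit4 was at 0.52 ± 0.20 and did not pass (0.975). Among the treatments Ddit4 was highest with Intralipos and Sgk1 lowest with O2, and both of these are controls. The differences may thus lie in the controls as much as in the anesthetics, and array set is confounded with the controls. Sgk1 and Ddit4 were the only genes past limma's test, with 754 at an unadjusted p under 0.05, 403 positive and 351 negative. The 754 are about the share that falls under 0.05 when no gene differs. Among genes that did not pass, the positive ones were Or4c110 (1.42 ± 0.26, 0.131), Slc35a2 (1.22 ± 0.23, 0.141), Gnat1 (1.22 ± 0.26, 0.295) and Oas1a (1.99 ± 0.42, 0.295). The negative ones were Plaat3 (-1.45 ± 0.27, 0.141), Akr1b7 (-0.95 ± 0.21, 0.407), Gpr50 (-0.82 ± 0.19, 0.571), Cntn6 (-1.10 ± 0.26, 0.589) and Ghdc (-0.85 ± 0.21, 0.589).

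**Figure D1:**
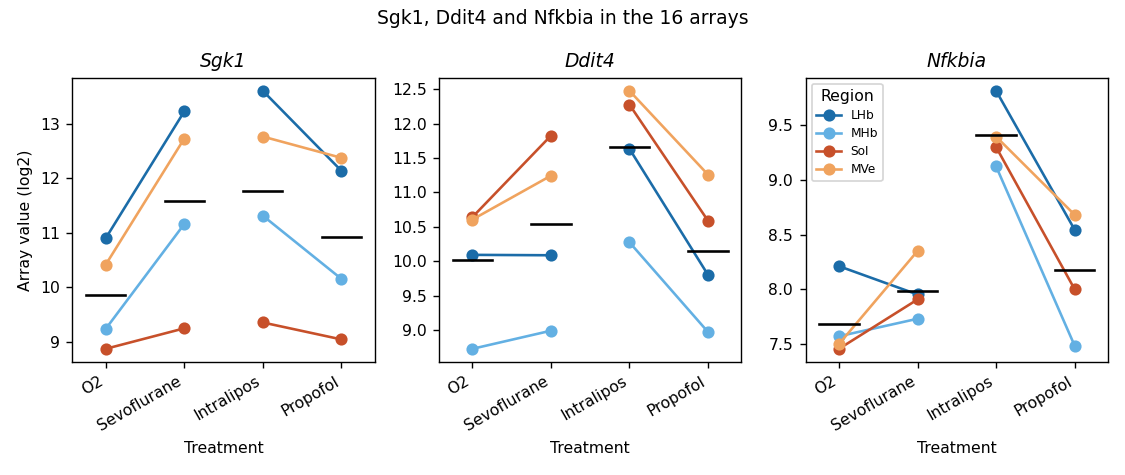
Array values (log2) of Sgk1, Ddit4 and Nfkbia by treatment, with 1 point per region, a line joining the arrays of an anesthetic and its own control, and a black bar at the mean of 4 regions. The O2 and Intralipos arrays belong to different array sets.

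Glucocorticoid-responsive genes differed between the anesthetics as a group, with 20 of 23 members positive and a median of 0.37 (camera adjusted p = 6.3e-11; adjusted p = 0.0056 with an estimated correlation). Of these 2 passed over all genes and 6 when adjusted over the list alone. Neuropeptide genes differed in the opposite direction, 24 of 28 negative with a median of -0.23 (1.6e-04; adjusted p = 0.0152 with an estimated correlation), although 0 passed over all genes or adjusted over the list alone. The somatostatin gene Sst (-0.93 ± 0.35), Penk (-0.89 ± 0.33), Pnoc (-0.85 ± 0.26) and the cholecystokinin gene Cck (-0.81 ± 0.32) had the largest values, each with an adjusted p of 0.946. By region, the neuropeptide medians in LHb, MHb, Sol and MVe were 0.06, -0.16, -0.33 and -0.11 after sevoflurane (percentiles 74.2, 1.95, 0.03 and 5.72) and 0.12, 0.06, 0.15 and 0.35 after propofol (93.8, 66.7, 94.9 and 100). Region markers differed in the Sol pairs, with solitary nucleus markers at -0.43 after sevoflurane (0.39) and Hox genes at 0.55 after propofol (99.99). FoxO and glucose-responsive genes were positive in 9 of 12 (median 0.21, 0.0021; adjusted p = 0.0686 with an estimated correlation), with 1 past the test over all genes and 2 adjusted over the list alone. That list shares Ddit4, Cdkn1a and Pdk4 with the glucocorticoid-responsive list. Pdk4 was at 0.93 ± 0.29 (0.946), Cdkn1a at 0.73 ± 0.33 (0.961) and Bcl6 at 0.66 ± 0.43 (0.994).

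Immediate early genes were positive in 34 of 45 (median 0.29, camera adjusted p = 1.7e-05; adjusted p = 0.579 with an estimated correlation), with 8 higher when adjusted over the list alone and 0 over all genes. Apold1 was at 2.07 ± 0.64, Dusp1 at 1.78 ± 0.60 and Ccn1 at 1.74 ± 0.54, each with an adjusted p of 0.946, and Nr4a1 at 1.54 ± 0.91 (0.994). Choroid plexus genes were negative in 9 of 11 (median -0.55, 2.0e-04; adjusted p = 0.579 with an estimated correlation), with Ttr at -2.95 ± 1.32 (0.952). Oligodendrocyte genes were negative in 12 of 13 (median -0.27, 0.0067; adjusted p = 0.598 with an estimated correlation), with Ugt8 at -0.84 ± 0.30 (0.946). In either of these 2 lists 0 members passed when adjusted over the list alone. The other lists had adjusted p-values from 0.215, for nicotinic receptor genes, to 0.924.

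The regions that stood in for replicates may share rats here too, so these p-values may be too small. The count of 2 genes became 0 without the MHb O2, LHb propofol, LHb Intralipos, MHb Intralipos, Sol propofol or MVe Intralipos array, 1 without the LHb O2, MHb sevoflurane, MVe sevoflurane or MHb propofol array, and 4 without the MVe propofol array. It became 1 with region within array set as the block, 0 over all probes that are not controls, and 4 with trend and robust variance estimates. The oligodendrocyte call was lost without LHb (0.189) or MHb (0.519), the FoxO call without MHb (0.108) and the choroid plexus call without Sol (0.111).

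Within single regions, the difference after sevoflurane of early genes such as Fos ran from -0.04 in LHb to 4.47 in MVe. These are differences between 1 array and 1 array, without a test. In MVe the sevoflurane array exceeded the O2 array by 5.23 for Nr4a1, 5.17 for Egr1, 4.47 for Fos, 4.05 for Apold1, 3.88 for Npas4, 3.02 for Junb and 1.88 for Arc, a synaptic early gene. In the same pair 11 of 13 neuron markers were above 0 (median 0.31, percentile 99.86) and 3 of 11 astrocyte markers were (median -0.19, percentile 0.25), and the MVe O2 array stood apart from the other O2 arrays in the interquartile range over genes (5.14 against 5.51 to 5.54). In Sol the differences were 3.91 for Egr1, 2.59 for Nr4a1, 2.47 for Fos, 2.28 for Junb, 0.94 for Arc and 0.69 for Npas4. In MHb they were 3.04 for Egr1, 2.79 for Fos, 2.40 for Nr4a1, 1.10 for Junb, 0.71 for Npas4 and 0.49 for Arc. In LHb Egr1 (1.49) and Junb (1.03) were higher, whereas Fos differed by -0.04, Npas4 by 0.04 and Arc by 0.43. Control levels also differed between regions. In the O2 arrays Egr1 stood at 10.80 in LHb, 7.38 in MHb, 8.29 in Sol and 7.53 in MVe. With sevoflurane it stood at 12.29, 10.42, 12.20 and 12.71 in that order. The smaller Egr1 difference in LHb thus goes with a higher control value, and a weaker response there cannot be told apart from it.

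After propofol, Egr1, Fos and Junb had their largest differences in MVe and LHb. In MVe the differences from Intralipos were 4.56 for Egr1, 2.86 for Nr4a1, 2.33 for Fos, 1.39 for Junb, 1.31 for Npas4 and -0.24 for Arc. In the same MVe pair the median was 0.96 for choroid plexus markers (11 of 11 above 0, percentile 100), -0.57 for blood cell genes (0.01) and -0.20 for astrocyte markers (1.93). In LHb they were 2.06 for Egr1, 1.85 for Jun, 1.84 for Fos, 1.35 for Junb, 0.81 for Npas4 and -0.18 for Arc. Tissue markers differed in the same LHb pair, with a median of 0.51 for medial habenula markers (percentile 100), -0.45 for thalamus markers (0.14) and -0.31 for astrocyte markers (0.03). In MHb the differences were 0.49 for Fos, 0.46 for Npas4, 0.11 for Egr1, 0.11 for Junb and -0.04 for Arc, and in Sol 0.87 for Egr1, 0.76 for Junb, 0.58 for Npas4, 0.30 for Arc and 0.25 for Fos.

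**Figure D2:**
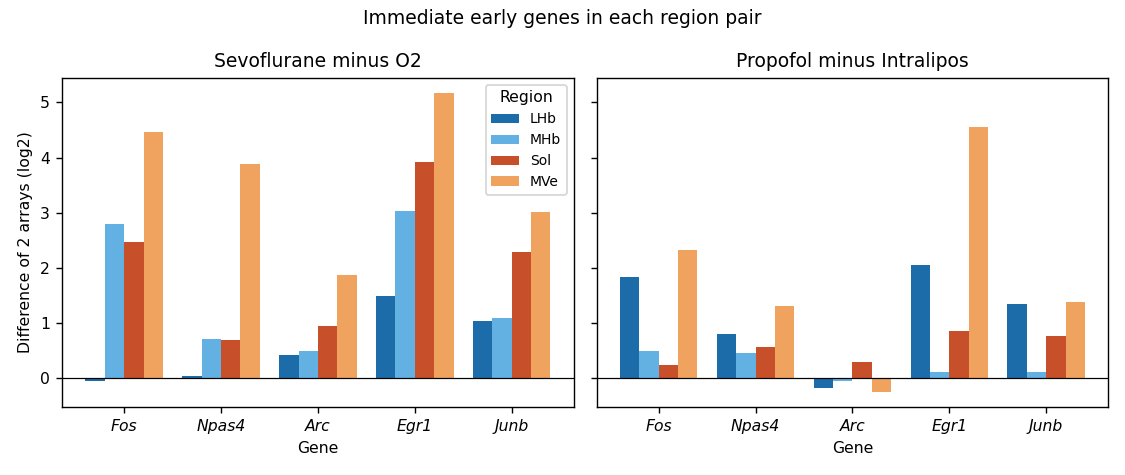
Difference between the anesthetic array and its control array (log2) for Fos, Npas4, Arc, Egr1 and Junb in each region, with 1 bar per region, sevoflurane minus O2 on the left and propofol minus Intralipos on the right. Each bar is a difference of 2 arrays with no replicate.

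Over the whole list, the immediate early genes had a median sevoflurane difference of 0.09 in LHb, 0.19 in MHb, 0.25 in Sol and 0.98 in MVe, at percentiles 91.5, 99.7, 99.97 and 100 of the random lists. After propofol the medians were 0.08, 0.11, 0.06 and 0.15 at percentiles 89.1, 88.4, 72.4 and 98.8. The glucocorticoid-responsive genes had sevoflurane medians of 0.30, 0.07, 0.38 and 0.44 at percentiles 99.95, 77.2, 100 and 99.98, and propofol medians of -0.16, -0.26, -0.22 and -0.19 at percentiles 1.98, 0.22, 0.58 and 2.56. Region markers moved in some of the same sevoflurane pairs, with medial habenula markers at 0.28 in LHb (percentile 99.66) and solitary nucleus markers at -0.43 in Sol (0.39). Sgk1 was higher after sevoflurane by 2.33 in LHb, 1.92 in MHb, 0.38 in Sol and 2.32 in MVe.

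Other genes were named for their large differences within a pair. After sevoflurane, LHb had Ercc1 (1.48) and Pld4 (1.38) higher, and the growth factor gene Fgf1 (-1.63), Cyp2j10 (-1.32), Ctxn3 (-1.28) and Cdk5rap2 (-1.28) lower. MHb had the GABA-A receptor subunit gene Gabrb2 (2.03) higher, and Irx5 (-1.69), the growth factor gene Igf1 (-1.39), Syt17 (-1.38) and Chst12 (-1.37) lower. Gabrb2 was 6.41 higher in LHb than in MHb over the treatments, so neighbouring tissue cannot be told apart from a response in that pair. Sol had Ttr (-2.92), the relaxin-family receptor gene Rxfp3 (-1.76), Wt1 (-1.51) and the hemoglobin gene Hba-a3 (-1.48) lower. MVe had Slc39a12 (-2.24), Idi2 (-1.77), Layn (-1.67) and Taar7g (-1.65) lower. After propofol, LHb had Syt15 (1.62) higher, and Ddit4 (-1.83), the thalamic marker gene Prkcd (-1.54), Filip1 (-1.48) and Sgk1 (-1.47) lower. MHb had the splicing factor gene Rbfox1 (1.74), Hunk (1.65), Rin2 (1.60) and Klhl20 (1.46) higher, and Slc35g1 (-2.67), Lgals3bp (-1.94), G2e3 (-1.91) and Cstb (-1.89) lower. Sol had Ttr (6.10), Saxo4 (2.44), Baiap2 (2.17) and Perp (2.04) higher, and Ddit4 (-1.69), Gadd45g (-1.65), Med20 (-1.55) and Iqcg (-1.48) lower. MVe had the cholecystokinin receptor gene Cckbr (1.72) higher, and Acp6 (-1.93), Ccdc51 (-1.48), Adck5 (-1.47) and Tnnt1 (-1.37) lower.

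Genes at least 2-fold apart after sevoflurane numbered 155 in LHb (81 higher, 74 lower), 223 in MHb (124, 99), 207 in Sol (106, 101) and 542 in MVe (296, 246). After propofol they numbered 235 in LHb (130, 105), 327 in MHb (165, 162), 377 in Sol (234, 143) and 256 in MVe (127, 129). The division depended on the scaling. With median centring it was 98 higher and 133 lower for sevoflurane in MHb, 164 and 414 for sevoflurane in MVe, and 161 and 202 for propofol in Sol.

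Whether the anesthetic effects differ between habenula and hindbrain was tested with 2 regions on each side. For sevoflurane, immediate early genes and oligodendrocyte genes were lower in the habenular effect than in the hindbrain effect. Early genes were negative in 36 of 45 (median -0.45, camera adjusted p = 8.4e-07; adjusted p = 0.377 with an estimated correlation), and without MVe the call was lost (0.187). Apold1 had the largest value (-2.48 ± 0.50, adjusted p = 0.735) and was the 1 member lower when adjusted over the list alone, against 0 over all genes. Nr4a1 (-2.44 ± 1.15, 0.927), Egr1 (-2.28 ± 1.19, 0.942) and Fos (-2.09 ± 1.16, 0.942) followed. The O2 value of Egr1 was higher in LHb (10.80) than in Sol (8.29) or MVe (7.53), though not in MHb (7.38). Oligodendrocyte genes were negative in 13 of 13 (median -0.51, 2.2e-05; adjusted p = 0.377 with an estimated correlation), with Gjb1 at -1.07 ± 0.44 (0.927). Within regions the oligodendrocyte medians after sevoflurane were -0.37 in LHb, -0.36 in MHb, 0.01 in Sol and 0.20 in MVe. The other lists had adjusted p-values from 0.0518, for nicotinic receptor genes, to 0.995. By limma 0 genes passed, with 803 at an unadjusted p under 0.05, and 1 passed without the Sol sevoflurane array. Those with the smallest p were Cyp3a62 (1.75 ± 0.36), Or9s15 (1.43 ± 0.30), Slc4a11 (1.33 ± 0.29), Rhox12 (1.33 ± 0.31), Ankra2 (1.16 ± 0.27), Myo19 (-1.76 ± 0.39), Nit2 (-1.30 ± 0.29), the endothelial gene Clec14a (-1.45 ± 0.33) and Vom2r16 (-1.40 ± 0.33), all at 0.735.

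For propofol, choroid plexus and microglia genes were lower in the habenular effect. Choroid plexus genes were negative in 10 of 11 (median -1.12, camera adjusted p = 1.6e-04; adjusted p = 0.569 with an estimated correlation), with Ttr at -3.09 ± 1.80 (0.932) and Clic6 at -1.52 ± 0.65 (0.918). Microglia genes were negative in 11 of 14 (median -0.55, 0.0058; adjusted p = 0.569 with an estimated correlation), with the complement genes C1qa at -0.92 ± 0.34 and C1qc at -0.88 ± 0.39 (both 0.918). The microglia call was lost without MHb (0.132) or Sol (0.293). In either list 0 members passed when adjusted over the list alone. The other lists had adjusted p-values from 0.0836, for solitary nucleus markers, to 0.998. By limma 0 genes passed, with 816 at an unadjusted p under 0.05. For both anesthetics the count under 0.05 is close to the share expected when no gene differs between habenula and hindbrain. The smallest p-values belonged to Tmem198b (-1.79 ± 0.28, 0.248), the sphingomyelin synthase gene Sgms2 (-2.08 ± 0.37, 0.467), Myo1f (-1.94 ± 0.36, 0.467), Unc5d (-1.41 ± 0.31) and the endothelial cadherin gene Cdh5 (-1.21 ± 0.27). On the positive side were Or5p69b (1.56 ± 0.35), Dgat1 (1.54 ± 0.35), Prss3 (1.61 ± 0.38), Apcs (1.39 ± 0.34) and Coa3 (1.11 ± 0.27), all at 0.849 with Unc5d and Cdh5. Regions of a side may share rats, so the p-values of both comparisons may be too small.

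The control treatments were compared to ask what the lipid vehicle adds to oxygen alone, but this comparison also sets 1 array set against the other. Relative to O2, the Intralipos arrays had Sgk1, Nfkbia and Ddit4 higher, and 9 of 14 microglia marker genes lower. Sgk1 was 1.91 ± 0.28 higher (adjusted p = 3.3e-04), Nfkbia 1.73 ± 0.19 (3.4e-05) and Ddit4 1.65 ± 0.20 (7.5e-05), each in 4 of 4 regions. The interferon-induced gene Mx2 (1.89 ± 0.31), the actin-associated gene Rai14 (1.70 ± 0.25), the axonemal gene Iqcg (1.64 ± 0.38), the meiotic gene Sycp2 (1.51 ± 0.17), Eif1b (1.41 ± 0.16), Or7g31 (1.35 ± 0.14) and Mtarc1 (1.34 ± 0.16) were also among the 10 highest, with adjusted p-values up to 0.0060. The 10 lowest were Prune1 (-2.02 ± 0.18), Evi2b (-2.01 ± 0.21), the mitochondrial RNA-binding gene Slirp (-1.97 ± 0.14), Gemin2 (-1.85 ± 0.18), L3hypdh (-1.84 ± 0.20), Syt8 (-1.78 ± 0.19), Lage3 (-1.76 ± 0.19), the Fc receptor chain gene Fcer1g (-1.73 ± 0.20), Ccdc77 (-1.72 ± 0.21) and Or1f29 (-1.70 ± 0.21), with adjusted p-values up to 1.0e-04. All of these had the same sign in 4 of 4 regions, which the naming rule requires.

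Limma called 3744 genes, 408 higher and 3336 lower with Intralipos (89.1% lower), of which 473 were at least 2-fold apart. The median over all genes was shifted by -0.21, and the changes and counts given here include that shift. With each array centred on its median, 2732 genes were called, 1955 higher and 777 lower (28.4% lower), and with quantile normalization 2053, 1077 higher and 976 lower. Among genes at or above the median level 2330 were called. Over all 4 treatments, 4734 genes differed by the moderated F test, 2969 with quantile normalization and 2992 at or above the median level. The F test also spans the array sets, which it cannot tell apart from treatment. Glucocorticoid-responsive genes were higher (16 of 23 above 0, median 0.18, camera adjusted p = 3.9e-05; adjusted p = 0.0720 with an estimated correlation), with 6 higher and 2 lower over all genes and the same counts adjusted over the list alone, and Pdk4 was 2.46-fold higher (5.3e-04). Microglia genes were lower (13 of 14 below 0, median -0.84, 0.0050; adjusted p = 0.377 with an estimated correlation), with 9 lower over all genes and 10 adjusted over the list alone. Among them the signalling adaptor gene Tyrobp was at -1.54 ± 0.18 (5.8e-05), Ptprc at -1.12 ± 0.21 (0.0014) and P2ry12 at -1.07 ± 0.21 (0.0018), and Itgam fell by 1.00 ± 0.26 (0.0107). Heat shock genes were higher (11 of 17 above 0, median 0.10, 0.0056; adjusted p = 0.377 with an estimated correlation), with 2 higher and 1 lower on either count. They were the co-chaperone gene Bag3 (0.60 ± 0.16, 0.0111), Hspd1 (0.55 ± 0.13, 0.0059) and Hspe1 (-0.42 ± 0.13, 0.0266). The other lists had adjusted p-values from 0.0563, for FoxO and glucose-responsive genes (median -0.02, with the test pointing higher), to 0.925. Treatment and array set cannot be told apart in this comparison, and its regions may share rats, so the p-values may be too small.

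LHb and MHb, adjacent parts of the habenula, were compared to show how distinct the dissected regions were. MHb was higher in medial habenula markers and nicotinic receptor genes, and LHb in GABA-A receptor subunit and endothelial genes. The LHb arrays were higher in Cbln1 (8.50 ± 0.21), Vsnl1 (7.70 ± 0.13), the GABA-A subunit genes Gabra5 (7.56 ± 0.19) and Gabrb2 (6.41 ± 0.28), Necab1 (7.16 ± 0.29), the growth cone gene Gap43 (6.75 ± 0.19), the calcium channel gene Cacna1i (6.45 ± 0.23), the muscarinic receptor gene Chrm2 (6.25 ± 0.22), Cacng2 (6.19 ± 0.16) and Itih3 (6.17 ± 0.18). The MHb arrays were higher in the nicotinic receptor gene Chrnb3 (-6.39 ± 0.25 for LHb minus MHb), Ttr (-6.10 ± 0.93), the glutamate transporter gene Slc17a7 (-5.91 ± 0.27), C1qtnf1 (-5.88 ± 0.27), Tac3 (-5.58 ± 0.37), Necab3 (-5.27 ± 0.20), the acetylcholine synthesis gene Chat (-5.26 ± 0.18), Cpne9 (-5.18 ± 0.21), Ano1 (-5.08 ± 0.16) and the acetylcholine transporter gene Slc18a3 (-5.03 ± 0.22). The largest adjusted p among these 20 genes was 5.1e-05, for Ttr, and all had the same sign under 4 of 4 treatments, which the naming rule requires.

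Between LHb and MHb 4289 genes passed, 2119 higher in LHb and 2170 higher in MHb (50.6% lower in LHb), and with median centring the share lower in LHb was 61.8% (1815 higher, 2936 lower). Camera called 17 of the 36 lists, and 4 with an estimated correlation. The medial habenula list fell in LHb (11 of 12 members, median -4.78, camera adjusted p = 3.3e-12; adjusted p = 0.0321 with an estimated correlation). Nicotinic receptor genes were lower in LHb (3.3e-05; adjusted p = 0.0427 with an estimated correlation), and GABA-A subunit genes (2.7e-08; adjusted p = 0.0149) and endothelial genes (3.0e-06; adjusted p = 0.0331) were higher. Their medians were -1.24, 1.78 and 1.12, and 7 of 11, 10 of 15 and 9 of 11 members passed in that direction, with the same counts adjusted over the list alone. Markers of other cell types moved as well. Astrocyte genes were higher in LHb (10 of 11, median 2.80, 5.3e-11; adjusted p = 0.0519 with an estimated correlation), led by the gap junction gene Gjb6 (5.95 ± 0.20). Oligodendrocyte genes were higher in 12 of 13 (median 1.84, 5.3e-11; adjusted p = 0.0519 with an estimated correlation), while ependymal (median -1.67, 9.8e-05; adjusted p = 0.0519) and choroid plexus genes (median -0.81, 0.0035; adjusted p = 0.319) were higher in MHb. Gpr151, placed among the lateral habenula markers, was higher in MHb (-2.26 ± 0.25, 1.0e-06). Treatments stood in for replicates and regions may share rats, so the p-values may be too small.

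The hindbrain regions differed as clearly. Sol was higher in monoamine and neuropeptide genes, and MVe in vestibular and glycinergic neuron genes and in oligodendrocyte markers. Sol was higher in Fam107a (8.25 ± 0.20), the noradrenaline synthesis genes Dbh (7.46 ± 0.26) and Th (7.02 ± 0.17), the peptide genes Nts (7.13 ± 0.21), Cartpt (6.96 ± 0.38) and Gal (6.76 ± 0.22), the patterning gene Hoxb5 (6.66 ± 0.22), the calcium-binding gene Calb1 (6.57 ± 0.16), Ppp1r17 (6.50 ± 0.15) and the potassium channel gene Kcnk2 (6.33 ± 0.32). MVe was higher in the calcium-binding gene Pvalb (-10.31 ± 0.28 for Sol minus MVe), Spp1 (-8.80 ± 0.26), the potassium channel gene Kcna1 (-7.55 ± 0.19), the sodium channel gene Scn4b (-7.01 ± 0.17), Cabp7 (-6.22 ± 0.21), Lamp5 (-6.20 ± 0.20), Inhba (-5.63 ± 0.21), Ttr (-5.63 ± 0.93), the neurofilament gene Nefh (-5.55 ± 0.16) and Syt2 (-5.33 ± 0.19). The largest adjusted p among these 20 genes was 1.0e-04, for Ttr, and all had the same sign under 4 of 4 treatments, which the naming rule requires.

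Between Sol and MVe 5300 genes passed, 2901 higher and 2399 lower in Sol (45.3% lower), and 61.4% were lower with median centring (2216 higher, 3526 lower). Camera called 13 of the 36 lists, and 7 with an estimated correlation. Vestibular and glycinergic neuron genes were lower in Sol in 12 of 12 (median -3.93, camera adjusted p = 1.7e-14; adjusted p = 9.6e-04 with an estimated correlation). Monoamine genes were higher (10 of 13 passed, median 2.24, 5.7e-10; adjusted p = 0.0010), as were neuropeptide genes (16 of 28, median 1.07, 2.2e-08; adjusted p = 0.0010) and solitary nucleus markers (7 of 9, median 3.89, 8.0e-08; adjusted p = 0.0342 with an estimated correlation). Adjusted over the list alone, 10 monoamine, 17 neuropeptide and 7 solitary nucleus genes were higher. The serotonin synthesis gene Tph2 (6.24 ± 0.20) and the tachykinin gene Tac1 (6.16 ± 0.31) were among them. Oligodendrocyte genes were lower in Sol (12 of 13, median -2.52, 4.4e-13; adjusted p = 0.0364), led by Ermn (-3.88 ± 0.15), and endothelial genes too (9 of 11, median -0.83, 6.8e-05; adjusted p = 0.0364). Microglia genes were higher in Sol (12 of 14, median 1.41, 1.4e-07; adjusted p = 0.0364), led by Csf1r (2.30 ± 0.19). Choroid plexus genes were lower in Sol (10 of 11, median -1.17, 6.6e-05; adjusted p = 0.291 with an estimated correlation). Treatments stood in for replicates and regions may share rats, so the p-values may be too small.

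The habenula as a whole was higher than the hindbrain regions in medial habenula markers and lower in vestibular and glycinergic neuron genes. The habenula was higher in Gpr151 (10.19 ± 0.18), Tac3 (8.92 ± 0.26), the G protein gene Gng8 (8.92 ± 0.22), the nicotinic subunit genes Chrnb3 (8.89 ± 0.18) and Chrna3 (7.44 ± 0.17), the transcription factor genes Lhx9 (7.69 ± 0.13) and Nr4a2 (7.43 ± 0.18), the serotonin receptor gene Htr5b (6.88 ± 0.15), Pde2a (6.82 ± 0.15) and Slc17a7 (6.56 ± 0.19). The hindbrain was higher in the GABA synthesis genes Gad1 (-9.33 ± 0.16) and Gad2 (-8.39 ± 0.20), Lamp5 (-7.14 ± 0.14), Mab21l2 (-7.08 ± 0.14), the glycine transporter and receptor genes Slc6a5 (-6.66 ± 0.20) and Glra1 (-6.59 ± 0.18), Cabp7 (-6.59 ± 0.15), C1ql3 (-6.34 ± 0.13), the vesicular GABA transporter gene Slc32a1 (-6.28 ± 0.13) and Penk (-6.20 ± 0.17). The largest adjusted p among these 20 genes was 1.0e-14, for Slc6a5, and all had the same sign under 4 of 4 treatments, which the naming rule requires.

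Between habenula and hindbrain 5736 genes passed, 2755 higher and 2981 lower in the habenula (52.0% lower), and 42.4% were lower with median centring (3420 higher, 2519 lower). Camera called 16 of the 36 lists, and 5 with an estimated correlation. Medial habenula markers were higher (11 of 12, median 4.66, camera adjusted p = 3.1e-16; adjusted p = 0.0118 with an estimated correlation), and vestibular and glycinergic genes were lower in 12 of 12 (median -3.65, 6.5e-16; adjusted p = 7.2e-04 with an estimated correlation). GABA-A subunit genes were lower (11 of 15, median -1.35, 1.2e-06; adjusted p = 0.0118), as were monoamine genes (8 of 13, median -1.35, 2.7e-04; adjusted p = 0.0193) and neuropeptide genes (16 of 28, median -0.47, 0.0010; adjusted p = 0.0202 with an estimated correlation). Adjusted over the list alone, 11 GABA-A subunit, 9 monoamine and 17 neuropeptide genes were lower. Hindbrain Hox genes were lower (9 of 10, median -1.58, 6.2e-07; adjusted p = 0.0596 with an estimated correlation), led by Hoxa2 (-5.45 ± 0.14). Astrocyte genes were lower (9 of 11, median -2.10, 7.4e-08; adjusted p = 0.0852), and blood cell genes too (6 of 9, median -1.84, 8.2e-04; adjusted p = 0.125 with an estimated correlation), with Hba-a3 at -2.82 ± 0.18. Treatments stood in for replicates and regions may share rats, so the p-values may be too small.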

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

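All weighed explanations, and the tests of them, were chosen after the results were seen, and the choroid plexus test across regions was revised after its first value was seen.

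A sample far from the other 3 of its group was found in 3 of 39 groups of 4. Chance gives about 1 in 20 groups among replicates, but these groups hold 4 different regions, so that share need not apply. The interquartile range over genes was 5.14 in the MVe O2 array, against 5.51 to 5.54 in the other O2 arrays, and 5.40 in the MVe sevoflurane array, against 5.52 to 5.55 in the other sevoflurane arrays. MVe also had the lowest range of the 4 regions with propofol (5.30) and with Intralipos (5.31), so part of this may belong to the region. The sevoflurane difference of Klri2 was -0.30 in LHb, against -0.71 to -0.74 in the other regions.

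The direct test found a difference between the anesthetic effects for Ddit4 (2.03) and Sgk1 (2.57). It also did so for the list medians of immediate early (0.29), glucocorticoid-responsive (0.37), FoxO-responsive (0.21), neuropeptide (-0.23), choroid plexus (-0.55) and oligodendrocyte genes (-0.27). With an estimated correlation 4 of these calls were lost, at adjusted p-values of 0.579 for immediate early, 0.0686 for FoxO-responsive, 0.579 for choroid plexus and 0.598 for oligodendrocyte genes. Between habenula and hindbrain, the sevoflurane effect differed for immediate early (-0.45) and oligodendrocyte genes (-0.51), and the propofol effect for choroid plexus (-1.12) and microglia genes (-0.55). These calls were all lost with an estimated correlation, at 0.377 for both sevoflurane lists and 0.569 for both propofol lists.

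The 3744 genes called between Intralipos and O2 divide arrays that also differ in their whole distribution. A single shift of each array is argued against as the whole cause, since 2732 genes were called after median centring. Of the 94 control probes without rat sequence, 30.9% had an unadjusted p under 0.05 in this contrast, fitted over all probes. Among the 15037 genes 5673 had one in the fit of genes. The control probes were fitted without centring, so they carry the offset between the array sets that was already known. They do not bear on the genes called after centring. An effect of the lipid emulsion cannot be told apart from a technical difference between the sets. The shift shared with propofol minus sevoflurane (r = 0.747 across genes) belongs to the set as much as to the lipid. The part of the 3744 genes due to either stays open.

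Choroid plexus genes in Sol had a median of -0.81 for sevoflurane minus O2 and 1.07 for propofol minus Intralipos. A propofol effect of the same size in all regions was compared with the habenular pairs, which cannot exclude it. The higher upper bound of LHb and MHb was 0.407, below the medians of 1.07 in Sol and 0.96 in MVe, and the MHb median lay at percentile 39.92 of random lists. These bounds take the 11 members of 1 array pair as replicates. Members such as Kcnj13 (4.24 with propofol, 3.43 with Intralipos) and Aqp1 (4.28, 4.39) were dim in LHb, where such an effect might not show. Unequal amounts of choroid plexus tissue in the dissected Sol samples may account for the values, with 10 of 11 members lower in the Sol sevoflurane array than in the Sol O2 array. Among the Sol arrays Ttr stood at 15.10 with O2, 12.18 with sevoflurane, 13.28 with propofol and 7.18 with Intralipos. The Sol propofol array was thus below the Sol O2 array for Ttr, and the Intralipos array was the lowest of the 4. The Ttr difference after propofol in Sol may therefore lie in a low control array. The O2 array belongs to the other array set. A propofol effect, in all regions or confined to the hindbrain, stays open.

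Glucocorticoid-responsive genes had a higher effect with sevoflurane than with propofol, each against its own control. Separate normalization of the array sets is argued against, since the adjusted p with an estimated correlation was 0.0042 after quantile normalization, and a constant offset between sets cancels in this contrast. More astrocyte tissue in some samples cannot be told apart from it, because the upper bound of the astrocyte genes (0.489) exceeded the list's own median of 0.37. The upper bounds of the endothelial (0.236) and microglia genes (0.301) lay below that median. All of these bounds take the members of a list as replicates, and the median they are set against has no error. They therefore do not exclude a part played by endothelial or microglial tissue. A difference between the control rats cannot be told apart either, since the list between Intralipos and O2 had an adjusted p of 0.0720 with an estimated correlation and array set is confounded with it. An effect of the anesthetics on stress hormones stays open and was not tested.

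Other splits of the same arrays bear on whether chance can be excluded. For sevoflurane the real split gave 0 genes, so that 35 of 35 splits gave as many by construction (8 in the highest other) and nothing follows about chance. For propofol 2 of 35 did (3, 10), and chance could not be excluded. The split with 10 genes set the 4 habenula arrays against the 4 hindbrain arrays, a structure of the samples by region, and every other split gave 0. The real split alone gave as many for Intralipos against O2 (1 of 35 splits; 3744, 2), LHb against MHb (1 of 35; 4289, 1) and Sol against MVe (1 of 35; 5300, 2). Most of these splits break the matching of the arrays by region or treatment, and swaps within the 4 matched pairs are too few for a share under 0.05 (0.125 at the least). Splits that shuffle regions within treatments excluded chance for habenula against hindbrain (1 of 100, with 5736 genes against 1118). For any treatment, splits that shuffle treatments within regions gave as many genes in 1 of 100 (4734 against 11). Those splits move arrays between the array sets, with which treatment is confounded, so nothing follows from them about chance for treatment alone. For the difference of the anesthetic effects, 5 of 100 unrestricted splits gave as many genes (2, 3027), so chance could not be excluded there. The 4 splits with more genes than the real one were those closest to the array set (alignment 0.75, on a scale where 1 is the set itself), and every other one gave 0. Splits within array sets, added after that result was seen, gave as many in 3 of 100 (2, 3). Since this second set of splits was chosen after the first, chance is not taken as excluded for these 2 genes.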

How the results depend on the processing

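The fits with region within array set as the block, the fits over all probes that are not controls, and the leave-out fits of lists were chosen after seeing the data; the other alternatives were planned. No named gene and no list reversed its direction. The side with more called genes depended on the scaling, which also changes which genes are called. Median centring gave 1955 higher and 777 lower for Intralipos against O2 (408 and 3336 without it), 2216 and 3526 for Sol against MVe (2901 and 2399) and 3420 and 2519 for habenula against hindbrain (2755 and 2981). Among genes 2-fold apart it gave 98 and 133 for sevoflurane in MHb (124 and 99), 94 and 113 in Sol (106 and 101), 164 and 414 in MVe (296 and 246), and for propofol 162 and 163 in MHb (165 and 162), 161 and 202 in Sol (234 and 143) and 134 and 118 in MVe (127 and 129). Quantile normalization gave 1077 and 976 for Intralipos against O2, 2155 and 2133 for LHb against MHb (2119 and 2170) and 177 and 192 for genes 2-fold apart with propofol in MHb. Among single genes, 1275 comparisons with an alternative kept their side of the threshold, 8 became stronger and 16 weaker. This tally leaves out the fits without single arrays and the fits of the compared groups alone. Many of its genes are region genes far from the threshold, which could hardly switch sides. It therefore says little about the few genes called for the anesthetics, whose counts in the fits left out are given below. Among list p-values 113 kept their side and 55 became weaker. The number of arrays limits the precision, and signal over background was not measured apart from the control probes. No paired analysis by rat was possible because the labels give no rat or replicate numbers; region is a term of the fits. The cause was not tested for any change below, except that fewer genes or arrays enter some fits.

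With trend and robust eBayes, sevoflurane gave 2 genes and the difference of the anesthetic effects gave 4. Propofol gave 1 gene in a fit of the 8 arrays of both groups alone and 1 over all probes that are not controls, and the difference of effects gave 1 with the block and 0 over all probes that are not controls. Intralipos against O2 gave 2053 genes and any treatment 2969 with quantile normalization, and 2330 and 2992 among genes at or above the median level.

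Genes at least 2-fold apart, among genes at or above the median level, numbered 36, 55, 54 and 183 for sevoflurane in LHb, MHb, Sol and MVe, and 99, 122, 141 and 66 for propofol. At 1.5-fold they numbered 1479, 1579, 1620 and 2621, and 1871, 2100, 2278 and 1935.

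Lists called with an estimated correlation, and with fry, numbered 1 and 1 for sevoflurane, 0 and 0 for propofol, 2 and 3 for the difference of effects, 0 and 17 for Intralipos against O2, 0 and 0 for the sevoflurane effect and 0 and 0 for the propofol effect in habenula against hindbrain. They numbered 4 and 29 for LHb against MHb, 7 and 25 for Sol against MVe, and 5 and 28 for habenula against hindbrain. Quantile normalization gave 3 lists for propofol.

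Leaving out 1 array or 1 region at a time, the count of genes ran from 0 to 8 for sevoflurane, 0 to 3 for propofol, 0 to 4 for the difference of effects, 2201 to 3358 for Intralipos against O2, 3153 to 4677 for any treatment and 0 to 1 for the sevoflurane effect in habenula against hindbrain. It stayed at 0 for the propofol effect in habenula against hindbrain. For any treatment no fit without region LHb was made. Between regions, with 1 array or 1 treatment left out, the count ran from 3533 to 3955 for LHb against MHb, 4383 to 4938 for Sol against MVe and 4769 to 5568 for habenula against hindbrain. With 1 region left out, lists called ran from 2 to 5 for sevoflurane, 1 to 5 for propofol, 4 to 6 for the difference of effects, 3 to 4 for Intralipos against O2, and 2 to 3 for the sevoflurane effect and 1 to 4 for the propofol effect in habenula against hindbrain.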

Other observations

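The interferon-stimulated gene list and its tests were chosen after the values were seen, as was the test of immediate early genes by region.

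Antiviral genes that interferons induce were low in the propofol arrays. Their median propofol difference was -0.56 in LHb, -0.55 in MHb, -0.38 in Sol and -0.12 in MVe, and their median sevoflurane difference was -0.05, -0.05, 0.53 and -0.03 in the same order. Over the 29 measured members other than the 6 noticed first, the mean deviation from the region's average was -0.27 ± 0.11 (SD over 4 regions) with propofol, 0.20 ± 0.12 with sevoflurane, 0.07 ± 0.08 with O2 and -0.00 ± 0.08 with Intralipos. Shuffling the treatments within regions gave a permutation p of 0.0011, but it moves arrays between the array sets, whose differences enter this p. Swapping each anesthetic with its own control within regions keeps the sets apart and gave an exact permutation p of 0.0312 over both anesthetics. The 29 members were measured on the same arrays as the 6 noticed first and may move with them. Neither p is therefore an independent test, and no conclusion is drawn from them. Alone, propofol minus Intralipos was at -0.27 ± 0.17 (SD over 4 regions; exact permutation p = 0.125, the smallest that 4 regions allow, with 4 of 4 below 0) and sevoflurane minus O2 at 0.13 ± 0.18 (exact permutation p = 0.250). A difference between rats is not separated from one between treatments. Tissue makeup is not separated either, since astrocyte markers were lower in the LHb and MVe propofol pairs and blood cell genes in the MVe pair.

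The immediate early genes had a sevoflurane median of 0.98 in MVe, with bounds of 0.43 and 1.54 over its members, against upper bounds of 0.26 in LHb, 0.51 in MHb and 0.61 in Sol. These bounds take the 45 members of 1 array pair as replicates. The O2 value of Egr1 was also higher in LHb (10.80) than in MVe (7.53). A response that is larger in MVe could not be tested against single arrays, and the test between habenula and hindbrain had an adjusted p of 0.377 with an estimated correlation.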
